A study of Mus musculus with 18 samples.

How the data were processed

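H3K4me3, a histone mark concentrated at active and poised promoters, was profiled by CUT&RUN, in which an antibody directs a nuclease that releases the chromatin around the mark. The nuclei came from mouse prospermatogonia, the fetal male germ cells that stop dividing before birth and regain DNA methylation, taken at embryonic day 17.5 as cells positive for an Oct4-GFP reporter. Each library was made from 4000 nuclei. The series held 18 samples: 9 with an H3K4me3 antibody and 9 with IgG, in 3 genotypes of 3 biological replicates per the labels. The genotypes were wild type (WT), Tet1 knockout (KO) and Tet1 HxD homozygotes (HxD), an allele altered in the catalytic HxD motif and known as catalytically inactive. All samples carried the same batch label. Only the 9 H3K4me3 libraries were analysed here, each from 1 deposited peak list, and the IgG libraries were not used here.

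Per the submitters' processing notes, the tools were Trim Galore, Bowtie2 2.5.0, SAMtools 1.16.1, bedtools 2.27.1, MACS2 2.1.0 and deepTools 3.5.1, and the genome build was mm10; the role and order of the tools are not given in the sources used here. The deposited lists are in the narrow peak format of MACS2, 1 list per library, so peaks were called per sample. Each peak carries the authors' score, a fold enrichment at the summit as a linear ratio over background, and −log10 p and −log10 q values. The smallest −log10 q in the deposited lists lay between 2.00 and 2.02, the mark of a q threshold of 0.01. The score, fold and −log10 values per peak are the authors' own. The −log10 q values served to filter and rank peaks within a list. The fold and p values gave a background, a mean coverage and summit heights per list, which were compared between libraries. No read counts or coverage tracks were analysed here, so the measurements are where peaks were called, how long they were and these recovered values. At most 6 peaks had the same coordinates in any pair of lists, so no list was a copy of another.

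Peaks on the 19 autosomes, X and Y were used. Coordinates are mm10, 1-based, and genes were taken from the RefSeq table of GRCm38.p6, the same assembly. That table gives no strand. The promoter of a gene was therefore taken as the 1 kb on either side of whichever gene end had more covered bp over all 9 libraries. Of 17212 coding genes with a peak at an end, 66.6% had peaks at 1 end only. The chosen end can be the promoter of a neighbour, and promoters inside a gene are not covered. Peaks of all libraries were merged into 186677 consensus regions, a library having a region when its peaks overlapped it by at least 1 bp. Regions were called promoter, gene body or intergenic with respect to coding genes. Promoter breadth was the covered bp within 5 kb of the gene end, for 16000 coding genes with a promoter peak in at least 3 libraries.

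The depth behind each list was recovered from its fold and p columns, which MACS2 computes from the summit height, the background and a scaling factor. On 3 simulated lists the background was recovered with an error of 0% and 95.2% to 100% of summits were solved. For the deposited lists 89.6% to 100% of peaks were solved. Background is the pileup expected at a position after scaling, mean coverage is that value before scaling, and summit height is given in multiples of the mean coverage of the library. Whether the IgG libraries were the controls of the calls is not given in the sources used here.

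Values per library were compared by two-sided exact permutation tests. With 3 libraries against 3 the smallest possible p is 0.1, with 3 against 6 it is 0.0119, and 1680 arrangements were enumerated for the F statistic over 3 groups. Breadth was compared with limma 3.58.1 in R 4.3.3 (linear model on bp over all 9 libraries, eBayes with trend, Benjamini-Hochberg adjustment, threshold 0.05). On libraries simulated for KO against WT, with 200 of 16000 genes narrowed, the test recovered 0% at losses of 500 bp and of 1000 bp, and 49.5% at 2000 bp. Gene lists were compared with limma's camera (preset correlation of 0.01, and an estimated correlation) and fry. The 11 lists held 422 symbols, of which 2 were absent from the gene table, and some genes were on more than 1 list. Noncoding members were added to the 16000 coding genes for the list tests. They were genes at maternally and at paternally methylated imprinted regions, meiotic genes, prospermatogonial and spermatogonial genes, pluripotency and primordial germ cell genes, developmental regulators, chromatin and DNA methylation enzymes, Sertoli, Leydig or interstitial, endothelial or blood markers, and housekeeping genes. List medians were also set against 10000 random lists of the same size matched on mean breadth and summit height. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

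The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named the TET and DNMT3 genes and the members of both imprinted lists. Per direction it named the coding genes past the breadth threshold whose libraries did not overlap between groups, those with the largest change up to 10 (5 for KO against HxD), and, where fewer than 5 passed, also the 5 with the smallest p. Symbols made of Gm and a number or ending in Rik were left out there and among the 5 broadest promoters in every library of a group and none of another. Up to 4 members per list with the smallest p in KO against WT were named, and, for each mutant against WT, the 3 regions per direction away from promoters with the most covered bp; 1 region that the rule names is left out of the text. The alternatives were stricter peaks (−log10 q of at least 5), lists of equal length (the 49624 peaks with the highest −log10 q), windows of 500 bp for promoters and 2 kb for breadth, other overlaps, a log2 scale with 200 bp added, centring each library, no filter, other limma settings, the replicate number as a block, and leaving out each replicate. A common summit height of at least 15 times mean coverage, the contrast of WT with the 6 mutant libraries, and the model of library ease were added after the data were seen. Which regions hold CpG islands was not analysed, as no genome sequence was used here.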

Results

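The question posed by the series title was how TET1, an enzyme that oxidises 5-methylcytosine, shapes chromatin in the male germline apart from its catalysis. The design set WT prospermatogonia beside cells without TET1 (KO) and cells with the HxD allele, with 3 H3K4me3 libraries each. The lists held 83586 to 128701 regions in WT, 69901 to 80232 in KO and 49624 to 67925 in HxD. The recovered background, which limits how weak a peak can be called, was 1.31 ± 0.385 in WT, 1.26 ± 0.273 in KO and 0.933 ± 0.308 in HxD (mean ± SD, n = 3 each). Mean coverage was 1.53 ± 0.186, 1.40 ± 0.132 and 1.65 ± 0.0541. The weakest 5% of summits in HxD replicates 2 and 3 lay below 10.2 and 10.1 times mean coverage, against 5.15 in WT replicate 3.

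The targeted gene, Tet1 (chromosome 10, 62804570 to 62887469), had a promoter peak in all 9 libraries. Its promoter breadth was 2767 ± 481 bp in WT, 3638 ± 1092 bp in KO and 3112 ± 475 bp in HxD (SD, n = 3 each). Neither mutant differed from WT by limma (adjusted p = 0.474 and 0.869). A promoter peak can remain when the coding part of a gene is deleted or altered, so this does not check the labels. Tet2, Tet3 and Dnmt3b also differed by less than the threshold in both mutants (adjusted p between 0.643 and 0.974 by limma). Dnmt3l, the cofactor of de novo methylation, had a breadth of 1196 ± 197 bp in WT, 1097 ± 295 bp in KO and 910 ± 423 bp in HxD (adjusted p = 0.910 and 0.771 by limma), and Dnmt3a was not tested because 1 library alone had a peak at the chosen gene end.

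Most marked promoters were shared by the 3 genotypes, and regions both at promoters and away from them were fewer in KO than in WT libraries. Of 21887 coding genes, 13043 had a promoter peak in all 9 libraries. Marked promoters numbered 15792 ± 507 in WT and 15199 ± 556 in KO (SD, n = 3 each; exact p = 0.4). Regions at promoters numbered 17467 ± 610.3 in WT and 14641 ± 397 in KO, 0.838 times as many (exact p = 0.1), and regions outside promoters 85136 ± 22880 and 59387 ± 5117, 0.698 times as many (exact p = 0.1). All regions together were 0.722 times as many in KO, covering 50.5 to 73.0 Mb against 76.6 to 108.9 Mb, and every KO library had fewer than every WT library (exact p = 0.1, the smallest that 3 against 3 allows). Over the 3 genotypes, an exact permutation F test gave p = 0.0036 for the region number and 0.0464 for the covered length. With lists of equal length, and at a common summit height, the order of marked promoters turned, to 1.15 and 1.04 times as many in KO.

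**Figure D1:**
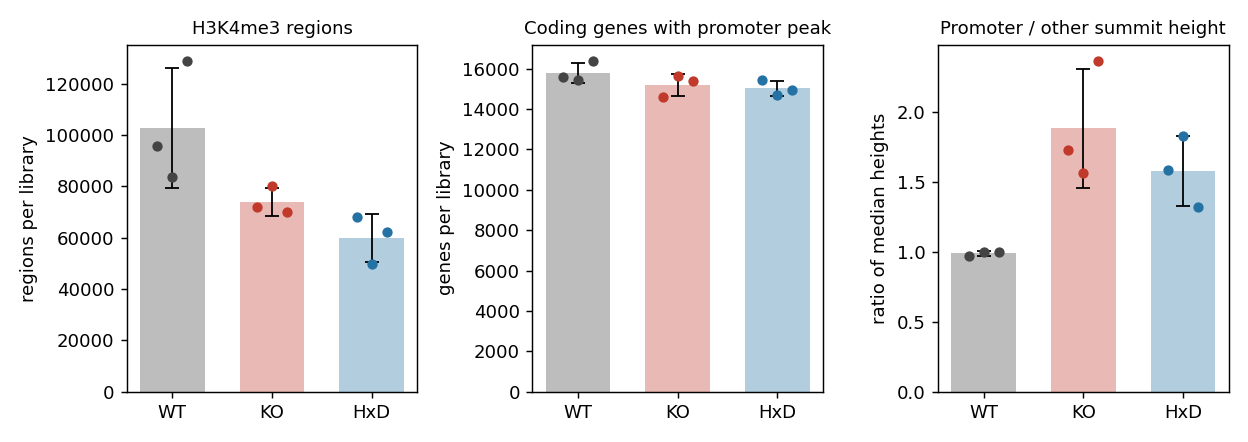
Regions per library, coding genes with a promoter peak per library, and the ratio of median summit height at promoters to that at other regions, both taken over regions shared by all 9 libraries. Points are libraries, bars are means and whiskers SD (n = 3); the height ratio lay between 0.969 and 1.00 in WT and between 1.32 and 2.37 in the mutants.

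Most regions that were in every WT and no KO library lay between genes. There were 6795 of them, of which 80.8% were intergenic, 17.1% in gene bodies and 2.12% at promoters, and 210 in the opposite direction. Of all 61558 regions in every WT library, 33808 were intergenic. Absent from every KO library were 16.2% of these, 8.25% of the 14068 in gene bodies and 1.05% of the 13682 at promoters. Among the longest by the naming rule were regions in gene deserts on chromosome 6 (9943717 to 9946012, between Nxph1 and Ndufa4), covering 2022 ± 235 bp in WT, and on chromosome 4 (27789911 to 27792461, between Manea and Epha7), 1849 ± 888 bp. No KO library had a peak in either, and 2 HxD libraries had a peak in each. Away from promoters, regions gained in every KO library lay between Dlk1 and Meg3 on chromosome 12 (described with the imprinted genes), inside Unc5b on chromosome 10 (60810974 to 60812710, 1101 ± 569 bp) and inside Sptb on chromosome 12 (76694192 to 76696014, 1091 ± 372 bp). Regions in every WT and no KO library were weak: 34.7% of regions whose lowest WT summit was under 10 times mean coverage were absent from every KO library, against 1.86% at 15 or more, where 574 remained. The reverse share at 15 or more was 0.031%. The count of 6795 was 13280 without KO replicate 2 and 11714 without WT replicate 2, since fewer libraries then had to be alike, and 1921 with lists of equal length. The count of 210 was 962, 533 and 511 without KO replicates 1, 2 and 3, 517 without WT replicate 3 and 907 with lists of equal length.

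**Figure D2:**
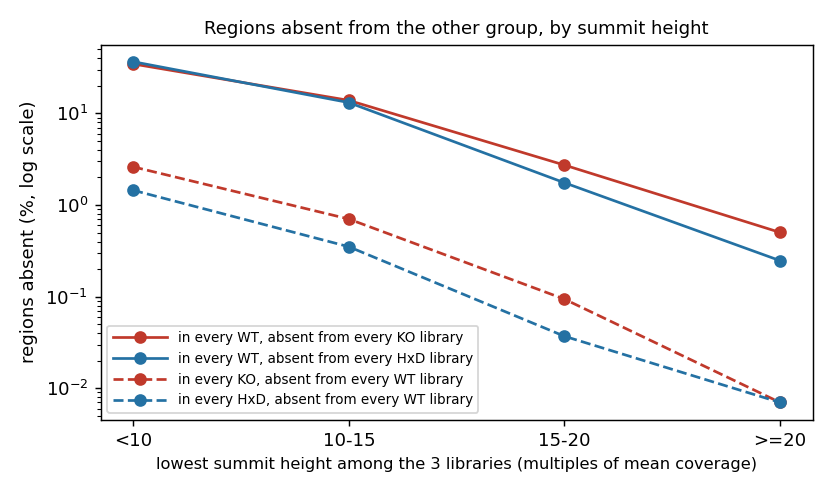
Share of regions present in every library of 1 genotype that had no peak in any library of the other (log axis, percent), by the lowest summit height among the 3 libraries that had the region, in multiples of mean coverage. In the lowest class 34.7% and 36.7% of WT regions were absent from KO and from HxD, and 2.61% and 1.45% of KO and HxD regions were absent from WT.

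At promoters, 137 of 14803 genes marked in every WT library had no promoter peak in any KO library. The broadest were Myl10, a myosin light chain (3309 ± 575 bp in WT, 675 ± 662 bp in KO within 5 kb), Shank3, a synaptic scaffold, Nhlh2, a neuronal transcription factor, Slc6a5, a glycine transporter, and Fkbp6, needed in meiosis. Within 5 kb Shank3 still had 2550 ± 454 bp in KO against 3115 ± 217 bp in WT, and Nhlh2 2255 ± 76.0 against 2566 ± 390.0 bp. In the other direction 18 of 14015 genes were marked in every KO and no WT library, led by Slc34a3, Mvp, Btbd10 (2301 ± 419 bp in KO and 2072 ± 272 bp in WT within 5 kb), Fcgr3 and Sfi1. The limma test of breadth called 1 promoter narrower in KO, that of Ankrd1, a cardiac ankyrin repeat gene on chromosome 19 (36111965 to 36119844), at 237 ± 411 bp against 2493 ± 417 bp in WT (difference −2256 ± 304 bp SE, adjusted p = 0.0431), lower in all 3 KO than in any WT library. That call was lost in 8 of the 9 fits that left out 1 library (adjusted p = 0.0541 to 0.158) and held without HxD replicate 1 (0.0479), where 2 promoters were called narrower. Over all alternatives its adjusted p ranged from 0.00529 to 0.196. None was called broader, and 3 were without KO replicate 1. At an unadjusted p under 0.05, 1192 promoters were narrower and 1082 broader. These unadjusted counts were 589 and 2475 with lists of equal length, 651 and 1958 without KO replicate 1 and 1231 and 434 without KO replicate 3. With the smallest p among those that did not pass, Ugt2a3, Olfr212, Krt26, Hnf4g and Myl10 were lower in KO (limma adjusted p = 0.0559 to 0.0572) and Il3ra, Rpl4 with its neighbour Zwilch (1 shared peak), Radil and Ube4b higher (0.0572 to 0.0756). After each library was centred on its mean over all tested genes, 281 promoters were called narrower and 183 broader, Nanog, Lefty1, Hcfc1, Setdb1 and Syce1 among the broader and Hoxa2, Hoxd3, Tbx5, Dlx2 and Dlk1 among the narrower. With lists of equal length the calls were 53 narrower and 240 broader, and with no filter 46 and 3.

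Gene lists moved apart in KO. Promoters of developmental regulators, the transcription factors and signals that pattern the embryo, were narrower, by a mean difference of −830.9 bp, with 101 of 117 lower (limma camera adjusted p = 2.61e-10, and 0.531 with an estimated correlation between genes). Without KO replicate 1 the mean was −339.8 bp. Relative to all genes, as camera compares lists, it was −866.6 bp and −577.3 bp without that library. Hoxa2 had 2095 ± 1339 bp in KO against 5083 ± 637 bp in WT, Hoxd3 2541 ± 1072 against 4494 ± 623, Dlx2 3070 ± 687 against 4778 ± 256 and Tbx5 656 ± 154 against 2508 ± 1157. Chromatin and methylation enzymes were on average 587 bp broader, with 42 of 46 higher (382 bp without KO replicate 3; camera adjusted p = 3.83e-06, and 0.531 with an estimated correlation); Hcfc1 had 3273 ± 661 bp in KO and 1479 ± 184 bp in WT, and Kmt2c, a histone H3K4 methyltransferase, 4227 ± 328 and 2706 ± 468. Housekeeping genes were 499 bp broader, 760.5 bp without KO replicate 1 and 242 bp without KO replicate 3 (37 of 44 higher; adjusted p = 9.57e-05, likewise 0.531). Pluripotency and germ cell genes were 598 bp broader, 908 bp without KO replicate 1 and 261 bp without KO replicate 3 (20 of 30 higher; adjusted p = 0.00301, likewise 0.531, and 0.109 with lists of equal length, in a range of 0.00133 to 0.109 over the alternatives), with Nanog at 3429 ± 1170 bp in KO and 1593 ± 435 bp in WT, and Pou5f1, whose reporter marked the sorted cells, at 3546 ± 1272 and 1922 ± 321.

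Markers of other cells of the fetal testis were narrower in KO alongside the developmental regulators by camera with its preset correlation, and with an estimated correlation none of these lists passed (adjusted p = 0.531 each). The preset calls were Leydig and interstitial genes (12 of 16 lower, among them Insl3 and Col1a1; camera adjusted p = 0.0102), Sertoli genes (12 of 15, among them Fshr and Sox9; 0.0234) and endothelial or blood genes (8 of 10, among them Kdr; 0.0234). The Sertoli call was lost without WT replicate 2 (0.0783), without KO replicate 1 (0.106) and with a 2 kb window (0.141), and the endothelial call without WT replicate 3 (0.0711). Over the alternatives adjusted p ranged from 0.00732 to 0.141 for Sertoli and from 0.0160 to 0.0711 for endothelial or blood genes. Meiotic genes (22 lower and 37 higher; 0.314) and prospermatogonial genes (18 and 18; 0.929) did not pass, although Nanos3 had 1680 ± 796 bp in KO and 506 ± 468 bp in WT. No list passed limma's fry, which tests a list without comparing it with other genes (smallest adjusted p = 0.384). After centring 7 lists passed fry: chromatin enzymes (0.00816), housekeeping, endothelial or blood and paternally methylated list genes (0.0119 each), and developmental regulators, pluripotency and Leydig or interstitial genes (0.0435 each). None passed camera with an estimated correlation after centring (smallest adjusted p = 0.101). No single member passed over all genes; adjusted over the list alone, 2 chromatin enzymes, 1 housekeeping gene and 1 meiotic gene were broader and 1 meiotic gene and 1 paternally methylated list member narrower.

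**Figure D3:**
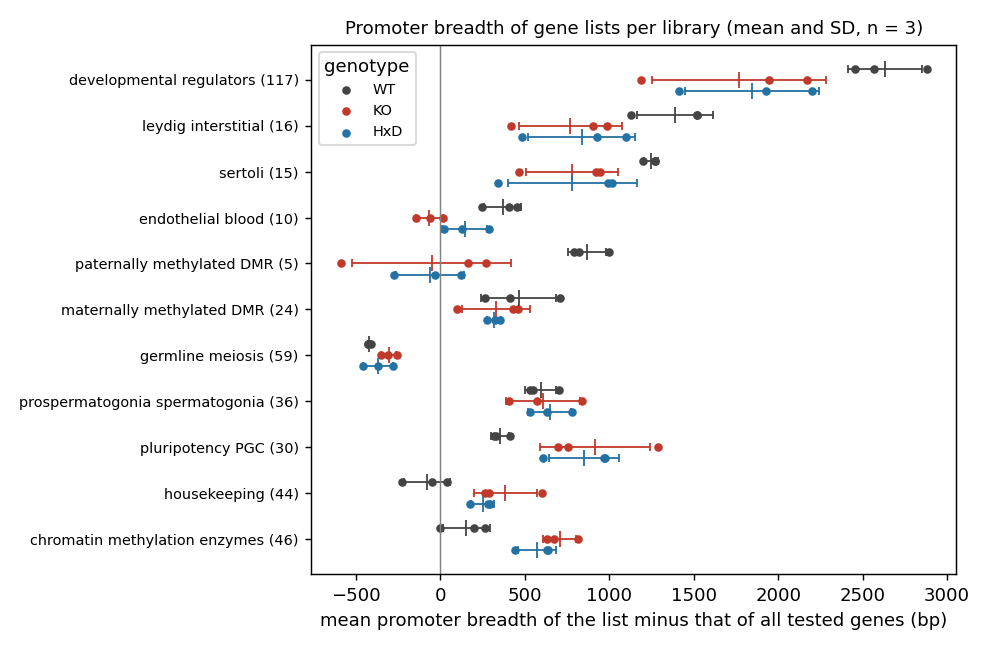
Mean promoter breadth of each gene list minus that of all tested genes in the same library (bp, horizontal axis), with the number of tested genes in brackets. Points are libraries, vertical ticks means and whiskers SD (n = 3 per genotype). Developmental regulators lay between 2456 and 2879 bp in WT and between 1188 and 2199 bp in the mutants.

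HxD libraries also had fewer regions than WT libraries, at promoters and away from them. Regions outside promoters numbered 45152 ± 8986 in HxD and 85136 ± 22880 in WT (SD, n = 3 each; exact p = 0.1), regions at promoters 14780 ± 649 and 17467 ± 610.3 (0.846 times as many; exact p = 0.1), and all regions were 0.584 times as many, with every HxD library below every WT library. Marked promoters numbered 15026 ± 366 (exact p = 0.2 against WT), and 1.15 times as many as in WT with lists of equal length. In every WT and no HxD library there were 6616 regions, 79.7% of them intergenic, and 66 in the reverse. Of regions in every WT library, 15.6% of the 33808 intergenic and 1.07% of the 13682 at promoters were absent from every HxD library. The longest away from promoters were on chromosome 14 (43121734 to 43125021 and 44246919 to 44249927) and chromosome 5 (23691527 to 23694755, beside Srpk2), with 2633 ± 422, 2424 ± 97.5 and 2248 ± 872 bp in WT. Both on chromosome 14 had a peak in all 3 KO libraries (1739 ± 593 and 1577 ± 62.1 bp), and that on chromosome 5 in 2. Regions in every HxD and no WT library were inside Dlg3 on chromosome X (100773932 to 100775093, 934 ± 232 bp), between Fcgr4 and Fcgr3 on chromosome 1 (171036640 to 171039700, 899 ± 746 bp) and between Dlk1 and Meg3. They were not particular to HxD. The regions inside Dlg3 and between Dlk1 and Meg3 had a peak in all 3 KO libraries, and that between Fcgr4 and Fcgr3 in 2. At 15 times mean coverage or more, 359 of 30950 WT regions were absent from HxD and 0.017% of HxD regions absent from WT. The 6616 became 11505 and 9925 without HxD replicates 1 and 3, 10104 and 12205 without WT replicates 1 and 2 and 1201 with lists of equal length. The 66 became 113, 238 and 308 without HxD replicates 1, 2 and 3, 126 and 227 without WT replicates 1 and 3 and 750 with lists of equal length.

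At promoters, 152 genes were marked in every WT and no HxD library, led by the protocadherin genes Pcdha7 and Pcdhb18 with Cfap73, F12 and Myl10, and 13 in every HxD and no WT library. The latter were led by Dnajc5, Dnajc1, Izumo1r and a peak shared by Sfi1 and Eif4enif1, which was in all 6 mutant and no WT libraries (1440 ± 356 bp in HxD, 1554 ± 734 bp in KO). Limma called no promoter narrower or broader in HxD, with 1446 narrower and 280 broader at an unadjusted p under 0.05. That tilt depended on scaling, with 586 narrower and 1502 broader for lists of equal length and 1211 and 1125 after centring. The smallest p among narrower promoters were those of Myl10, Zfp354a, Gpx6, Olfr212 and Grm5 (adjusted p = 0.0796 each), and among broader ones those of Ep300, a histone acetyltransferase, Sfi1, Eif4enif1, Bahcc1 and Thoc2 (adjusted p = 0.0959 to 0.219). Without KO replicate 1 in the shared fit 22 were called narrower and 3 broader, after centring 43 and 12, with lists of equal length 1 and 3 and with no filter 38 and 0.

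Developmental regulators were narrower in HxD too, by a mean difference of −934.7 bp (106 of 117 lower; camera adjusted p = 6.34e-08, and 0.626 with an estimated correlation), with Hoxd3 at 2122 ± 263 bp and Hoxa2 at 2981 ± 1162 bp. Sertoli genes were narrower (13 of 15; 0.0130, likewise 0.626), a call lost without WT replicate 2 (0.0505) and without HxD replicate 2 (0.145). Leydig and interstitial (15 of 16 lower; 0.0540) and endothelial or blood genes (9 of 10 lower; 0.171) did not pass, though the former did without WT replicate 2 (0.0290), KO replicate 1 (0.0436) or 3 (0.0495) or HxD replicate 1 (0.0276) or 3 (0.0319), and with stricter peaks (0.0270), lists of equal length (0.0110), a 2 kb window (0.0204) or centring (0.0141). Over the alternatives adjusted p ranged from 0.00345 to 0.145 for Sertoli, 0.0110 to 0.243 for Leydig and interstitial and 0.000281 to 0.120 for pluripotency genes. Chromatin enzymes (30 of 46 higher; 7.99e-05), housekeeping genes (26 of 44; 0.00114) and pluripotency genes (17 of 30; 0.00114, and 0.120 with lists of equal length) were broader, each at 0.626 with an estimated correlation. Nanog had 2955 ± 255 bp and Pou5f1 3225 ± 605 bp. Meiotic (0.716) and prospermatogonial genes (0.450) did not pass. Their means lay below 0, at −94.55 and −93.43 bp, and above the mean of −146.4 bp over all genes, with which camera compares them (35.7 bp in KO). The means of both lists were above 0 without WT replicate 3 (46.3 and 103.0 bp) or HxD replicate 3 (29.2 and 44.0 bp). No list passed by fry (smallest adjusted p = 0.394), and after centring chromatin enzymes and the paternally methylated list did (0.0210 each). No member passed over all genes; adjusted over the list alone, 1 developmental regulator and 2 paternally methylated list members were narrower.

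Among imprinted genes, those at paternally methylated regions were narrower in both mutants by camera, though not with an estimated correlation (adjusted p = 0.531 and 0.626), with Dlk1, a growth regulator expressed from the paternal allele, and its neighbour Meg3 the furthest from WT. The median of the list lay within the range of random lists matched on breadth and summit height, at −562.7 bp in KO (percentile 12.2) and −631.3 bp in HxD (16.3). Dlk1 (chromosome 12, 109452485 to 109463336) had 3928 ± 481 bp in WT, 2266 ± 508 bp in KO and 2238 ± 762 bp in HxD (limma adjusted p = 0.146 and 0.219, not passing over all genes). Rasgrf1 had 3457 ± 130, 2894 ± 308 and 2915 ± 400 bp, and Zdbf2 1523 ± 672, 1245 ± 732 and 892 ± 368 bp. Zdbf2 was measured at 1 end of its gene model, and regions inside the gene went both ways. The region at 63272226 to 63274832 had 1839 ± 402 bp in WT, 2007 ± 486 in KO and 2216 ± 226 in HxD. That at 63246826 to 63249282 had 1722 ± 467, 1259 ± 1101 and 1158 ± 413 bp. All 5 tested members were lower in KO (mean −884.5 bp, and −413.7 bp without KO replicate 1; camera adjusted p = 0.0162) and in HxD (mean −1077 bp; 0.0110). The call was lost with lists of equal length (0.125 and 0.157) and, in KO, without KO replicate 1 (0.0516). Without that library H19 lay above its WT mean in KO, so the count of 5 lower members in KO rests on KO replicate 1. Over the alternatives adjusted p ranged from 0.00564 to 0.125 in KO and from 0.00221 to 0.157 in HxD. Meg3 had 3840 ± 692 bp at its end in WT, 2176 ± 1952 bp in KO and 1850 ± 614 bp in HxD, and H19 1838 ± 557, 1582 ± 1376 and 1306 ± 219 bp. These noncoding genes were outside the coding genes tested singly. The Meg3 mean in KO was lowered by KO replicate 1, with 0 bp in the region at that end, against 2755 and 3539 bp in KO replicates 2 and 3. Gpr1 and Rtl1 had no promoter peak in any library and were not tested.

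The intergenic region at 109527294 to 109530501 on chromosome 12, 10495 bp from Meg3 and 63957 bp from Dlk1, lies in the interval that holds the imprinting control region of this cluster, which is methylated in sperm. It had no peak in any WT library. Peaks covered 1251, 653 and 3208 bp of it in KO replicates 1, 2 and 3 and 1704 ± 1336 bp on average, and 873 ± 956 bp in HxD, with a peak in all 6 mutant libraries.

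**Figure D4:**
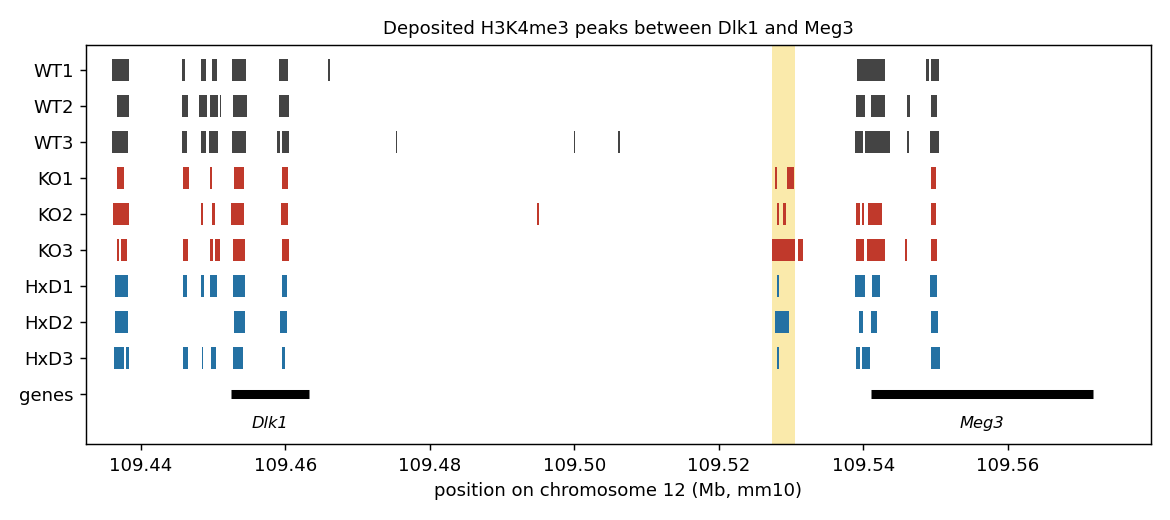
Deposited H3K4me3 peaks on chromosome 12 from before Dlk1 to after Meg3 (mm10, Mb), 1 line per library, with gene bodies as black bars. The shaded region, 109527294 to 109530501, holds peaks in the 6 mutant libraries and in no WT library.

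Genes at maternally methylated imprinted regions did not differ as a list. Their mean difference was −97.83 bp in KO (12 lower and 12 higher of 24; camera adjusted p = 0.562) and −291.6 bp in HxD (19 lower, 5 higher; 0.282). In KO it was above 0 without KO replicate 1 (220.1 bp) or WT replicate 3 (21.4 bp). In HxD it ranged from −457.3 bp without WT replicate 1 to −172.4 bp without WT replicate 3. Zrsr1 had 2136 ± 217 bp in WT and 3108 ± 570 bp in KO (limma adjusted p = 0.251), Ndn 1880 ± 535 and 1250 ± 237 bp (0.377), Grb10 2776 ± 991 and 3484 ± 470 bp (0.536) and Gnas 3441 ± 664 and 2687 ± 695 bp (0.489). Peg3 and Usp29, which share a promoter, had 3763 ± 585 bp in WT, 3602 ± 1098 bp in KO and 3495 ± 211 bp in HxD. Mest, Igf2r, Impact, Plagl1, Peg10 with Sgce, Mcts2, Nnat, Nap1l5, Slc38a4, Cdh15, Magel2, Peg12, Mkrn3 and Inpp5f also missed the threshold in both mutants (limma adjusted p from 0.412 to 0.988). The noncoding genes Airn, Kcnq1ot1 and Peg13 had a promoter peak in all 9 libraries, and Snrpn, with a promoter inside its long gene model, is listed at 0 covered bp.

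Region numbers of KO and HxD lay closer to each other than to WT, and that difference of differences was not tested. KO had 1.24 times as many regions (exact p = 0.1), and marked promoters numbered 15199 ± 556 and 15026 ± 366 (exact p = 0.8). In every KO and no HxD library there were 507 regions, and 286 in the reverse, an order that turned with lists of equal length (325 and 545) and at a common summit height (8 and 13). The model in which libraries differ only in ease of calling expected 1415 and 137. The 507 became 2414, 1077 and 1447 without KO replicates 1, 2 and 3 and 1517, 763 and 870 without HxD replicates 1, 2 and 3. The 286 became 505, 1581 and 648 without HxD replicates 1, 2 and 3 and 1380 and 591 without KO replicates 2 and 3. At promoters, 26 genes were marked in every KO and no HxD library, led by Mea1, Rnf212b, Slc34a3, Pcdha7 and Pcdh9, and 10 in the reverse, led by Klrg2, Btnl10, Filip1, Soat2 and Slco6d1. Within 5 kb Klrg2 had 2490 ± 284 bp in KO and 2498 ± 598 bp in HxD. Limma called no promoter different, with 35 narrower and 430 broader in KO at an unadjusted p under 0.05 and adjusted p = 1.0 for the genes named. After centring the unadjusted counts were 284 narrower and 332 broader. Filip1, Bhlha9, Islr, Olfr544 and Chga had the smallest p among those narrower in KO, and Nxf2, Ppp1r17, Itgad, Cox6a2 and Nt5el among those broader. Nxf2 had 1459 ± 398 bp in KO and no covered bp in HxD. No gene list passed camera. Developmental regulators had a mean of 103.8 bp, below the 182.1 bp of all genes (adjusted p = 0.0692), and passed without KO replicate 2 (0.000417) or HxD replicate 2 (0.000121). Leydig and interstitial genes passed without HxD replicate 2 (0.0408). Over the alternatives these adjusted p ranged from 0.000121 to 0.862 and from 0.0408 to 0.555. At a common summit height the region number turned to 0.889 times as many in KO.

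Across genes, the breadth differences of KO and of HxD from WT had a correlation of 0.825, against 0.500 in 50 simulations of unchanged groups sharing the WT libraries. The covariance was 246949 against a simulated 94182. Genes are not independent replicates, and the simulation drew every gene in every library independently. It lacked deviations shared by the genes of a library, which can raise both values. The excess therefore does not show an effect common to the mutants. With no promoter called in HxD none was called in both mutants, and where both had calls the number shared was 44 (centred), 23 (no filter), 4 (lists of equal length) and 3 (without KO replicate 1). Of 61558 regions in every WT library, 3408 were absent from all 6 mutant libraries, against 730.3 for independent lists and 823 from a model in which libraries differ only in ease of calling. Regions weak in WT were absent more often from both mutants. With the lowest WT summit under 10 times mean coverage, 34.7% were absent from every KO and 36.7% from every HxD library. At 20 or more these shares were 0.502% and 0.247%. The number for independent lists ignores region strength, so the excess over it does not show an effect common to the mutants. The 3408 became 5664 and 6986 without WT replicates 1 and 2, 5306 with peaks covering at least 50% of a region and 555 with lists of equal length. Pooled over genotypes, libraries of the same genotype shared more covered sequence than those of different genotypes, by a mean Jaccard index of 0.0460 (exact one-sided permutation p = 0.0143). The index cannot exceed the ratio of the covered lengths of 2 lists, which were 76.6 to 108.9 Mb in WT and 45.6 to 69.3 Mb in HxD. The difference is therefore not separated from list length. That index was 0.514 within WT and 0.506 within HxD, but 0.436 within KO, below the 0.474 of pairs of a KO and an HxD library. KO replicate 1 stood apart, at 0.387 and 0.392 with KO replicates 2 and 3, which had 0.528 with each other. Pairs with WT had 0.409 (KO) and 0.435 (HxD).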

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

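The counts under other splits and the tests of calling depth, library ease, library contrast, the regions in mutants alone, Meg3 and Dlk1 were chosen after the results were seen (for the regions in mutants alone, the ratio to library ease after the count), and the matched random lists were set out before their percentiles, though not before the list means, were seen. Peaks outside the numbered chromosomes, X and Y entered no comparison: the lists held 39, 42 and 75 such peaks in WT, 30, 26 and 21 in KO and 25, 11 and 19 in HxD, and no control list was used to judge them. Groups of 3 were too small for a test of outlying libraries.

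Regions in every WT and no mutant library numbered 3408, and 1 of the 84 choices of 3 libraries, the real one, gave as many (highest other 810), a count that also follows the length of the lists. Calling depth as the whole cause is argued against by KO replicate 3 and HxD replicate 1, which had higher coverage and background than WT replicates 1 and 2 and yet at most 0.836 times the regions of the lower of these. A model in which libraries differ only in ease of calling expected 823 regions, a ratio of 4.14 that no other choice reached (highest 3.29). The same model misses some combinations by more. For regions absent only from KO replicates 1 and 3 and HxD replicate 2 the ratio was 5.57. The rank of the real choice therefore does not exclude chance. Taken singly the ratio was 3.85 for KO but 1.75 for HxD, below the 2.09 found for HxD against KO, so for HxD alone ease of calling could account for more of the count. A lower contrast of WT libraries remains open: the promoter to other height ratio was lower in every WT than in every mutant library (exact permutation p = 0.0119), which goes with genotype and cannot be told apart from it.

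Developmental regulator promoters were narrower in both mutants. Of 10000 random lists matched on mean breadth and summit height, 0% had a median as low. In the same test chromatin enzymes (percentile 100.0 in KO, 99.99 in HxD) and housekeeping genes (100.0 and 99.96) lay at the opposite end. The random lists lacked the correlation within a list, estimated at 0.492 for developmental regulators, so their range can be too narrow. The test therefore argues against promoters of that shape in general only as far as genes vary independently. Whether the lower contrast of WT libraries shifts these lists was not tested. For developmental regulators the camera calls were lost with an estimated correlation (adjusted p = 0.531 in KO and 0.626 in HxD). Their list means in WT and mutant libraries overlapped (exact permutation p = 0.0952). Relative to all genes they did not overlap, at 2456 to 2879 bp in WT and 1188 to 2199 bp in the mutants (exact permutation p = 0.0357). A candidate explanation is more somatic cells in the WT preparations. The median of 40 Sertoli, interstitial, endothelial and blood markers lay at the 0.32 percentile of matched lists in HxD and lower in KO. The endothelial and blood list by itself lay at 26.2 in HxD, and the same limit of the random lists holds here. The means of the 40 markers overlapped between WT and mutant libraries (exact permutation p = 0.143), though not relative to all genes (exact permutation p = 0.0238). The number of markers with a promoter peak overlapped too. For Sertoli genes it was 14 to 15 in WT, 14 to 16 in KO and 12 to 14 in HxD. For endothelial or blood genes it was 10 to 13, 10 to 12 and 9 to 10. The Oct4-GFP sort is meant to remove somatic cells, but its purity per preparation is not given in the sources used here. Expression in prospermatogonia was not analysed here. The Leydig gene Insl3 had 5977 ± 1773 bp in WT and 3495 ± 1575 bp in KO, and the Sertoli gene Sox9 4388 ± 806 and 3280 ± 1090 bp. The meiotic and prospermatogonial lists lay at percentiles of 95.9 and 42.4 in KO, and an effect of TET1 on these promoters was not separated from the share of somatic cells and stays open as a hypothesis.

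The region between Dlk1 and Meg3 was 1 of 20 present in all 6 mutant and no WT libraries. A count of 20 is reached by 47 of the 84 choices of 3 absent libraries but follows the length of the lists. Relative to library ease 2 choices reached the ratio of 5.02. The other choice (KO replicates 1 and 3 with HxD replicate 2, 1567 regions, 5.57) points to a structure of the libraries apart from genotype. This share of choices therefore does not exclude chance. Poor detection of the region in WT is not settled by its neighbours. Dlk1, 63957 bp away, had 3402 bp or more in every WT and 2967 bp or less in every mutant library, 435 bp apart (exact permutation p = 0.0119). Its promoter itself separated the genotypes, so it cannot show whether a peak in the region would be called in WT. The region at the end of Meg3 was wider in WT on average, 3840 against 1974 bp (exact permutation p = 0.0476). There the lowest WT library lay below the highest mutant library, with a difference of −381 bp. Altered methylation of the imprinting control region may underlie the peak as a hypothesis, and no methylation data were analysed here.

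For the all-or-none regions, 10 splits of 6 libraries are too few for a share under 0.05. The real KO and WT split gave 7005 regions with the highest other 1891 (1 split as large), HxD and WT 6682 with 1604 (1 split), and KO and HxD 793 with 2134 (6 splits). In the breadth test fitted to 6 libraries, all 10 splits gave 0 promoters in each comparison, so nothing follows from them. WT against the 6 mutant libraries gave 64 narrower and 4 broader promoters, and 2 of 84 splits gave as many. The other split, KO replicate 1 with HxD replicates 2 and 3 from the rest, gave 151. That points to a structure of the libraries apart from genotype, so this share of splits does not exclude chance.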

How the results depend on the processing

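The common summit height was chosen after the data were seen, as was the result on regions in every WT and no mutant library with its alternatives. The most upstream start site was not run because the gene table has no strand, and equal lists give no region number. The ratios of region number and covered length of each mutant to WT kept their direction in every setting and replicate left out that was run. Covered length came closer to WT with equal lists, from 0.718 to 0.898 in KO (exact p = 0.6) and from 0.627 to 0.844 in HxD (exact p = 0.3). Region number ranged from 0.660 to 0.827 in KO and 0.535 to 0.669 in HxD without single replicates, and was 0.655 and 0.603 with stricter peaks and 0.654 and 0.736 at a common height. Marked promoters turned with equal lists to 1.15 in both KO and HxD, and at a common summit height to 1.04, 1.06 and, for KO over HxD, 0.985, where the region number of KO over HxD became 0.889; the cause was not tested. Without single replicates marked promoters of KO over HxD ranged from 0.997, without KO replicate 2, to 1.03. The WT minus mutant difference in promoter share, −4.91 percentage points (exact p = 0.0714), was −7.59 with stricter peaks (0.0357), −3.15 with equal lists (0.0119) and −12.2 at a common height (0.0357); the cause was not tested.

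All-or-none counts depended on which peaks were kept; the cause was not tested. With equal lists they were 1921 (WT not KO), 907 (KO not WT), 1201 (WT not HxD), 750 (HxD not WT), 545 (HxD not KO), 325 (KO not HxD) and 555 (WT and no mutant). At a common height they were 574, 6, 359, 4, 13, 8 and 102 in that order. With peaks covering at least 50% of a region, HxD not WT was 116 and WT and no mutant 5306. Leaving out replicates gave 8095 to 13280, 277 to 962, 7504 to 12205, 99 to 308, 407 to 1581, 763 to 2414 and 3567 to 6986 in that order, because fewer libraries then had to be alike.

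Breadth calls depended on scaling. The 1 narrower promoter in KO was 0 with a 2 kb window, stricter peaks, the log2 scale, eBayes without trend, only the 6 libraries or the replicate block, 53 with equal lists, 281 centred and 46 with no filter, and 0 to 2 without single replicates. Broader in KO gave 240, 183 and 3 with equal lists, centred and no filter, and 0 to 3 without single replicates. Narrower in HxD gave 1, 43 and 38 and 0 to 22, and broader in HxD 3 with equal lists, 12 centred and 0 to 3. Calls shared by both mutants were 4, 44 and 23 with equal lists, centred and no filter, and 0 to 3 without single replicates. Lists past the camera threshold ranged from 6 to 8 in KO, 5 to 7 in HxD and 0 to 2 in KO against HxD without single replicates. For single lists, 439 of 462 alternatives gave the same call, and for the named genes 3994 of 4104, with 0 reversed. Missing the threshold in both fits counted as the same call. Among the named genes only Ankrd1 in KO was called in the main fit, so nearly all of that agreement was of this kind. Of the other alternatives for named genes, 14 lost a call and 96 gained 1.

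The replicate numbers did not pair the libraries: deviations of same-numbered libraries had correlations of −0.236 to 0.080, and 1 of 9 libraries was closest to its own number. With the replicate number as a block, 0 promoters were called in every comparison, no list count changed, and the exact sign-flip test of 3 pairs cannot go below p = 0.25. The scaled background, which limits how weak a peak can be called, was lowest in HxD replicates 2 and 3 (0.675 and 0.852), although their mean coverage (1.67 and 1.59) lay above that of WT replicates 1 and 2 (1.44 and 1.41).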

Other observations

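The tests of the X chromosome share and of summit heights were chosen after the data were seen. Regions on the X chromosome made up 3.49% ± 0.525 of regions in WT, 2.73% ± 0.0367 in KO and 2.37% ± 0.0527 in HxD (SD, n = 3 each), lower in all 6 mutant libraries than in any WT library (exact permutation p = 0.0119, the smallest that 3 against 6 allows). The share broadly followed list length. Within WT it was 4.01% in replicate 3 (128701 regions) and 2.96% in replicate 2 (83586 regions). It was lowest, at 2.32%, in HxD replicate 2, which had the fewest regions (49624). Within KO and within HxD the order of the libraries was not kept. The share was not tested with lists of equal length, so the difference is not separated from list length. At promoters shared by all 9 libraries the median summit height was 20.5 to 24.01 times mean coverage in WT libraries, 37.3 ± 8.27 in KO and 32.8 ± 5.06 in HxD. At other shared regions it was 22.2 ± 1.74 in WT, 19.9 ± 2.86 in KO and 20.8 ± 0.659 in HxD.

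Of the 20 regions in all 6 mutant and no WT libraries, 5 were at promoters, 9 in gene bodies and 6 between genes. Those at promoters were beside Wdr64, Usp11, Pbdc1 and Snrnp70 and at the shared promoter of Sfi1 and Eif4enif1, all chosen for mention after their values were seen. Usp11 (chromosome X, 20703442 to 20705293) covered 1310 ± 461 bp in KO and 959 ± 578 bp in HxD, and Pbdc1 (chromosome X, 105078893 to 105080763) 1152 ± 728 and 795 ± 454 bp.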
